A study of Mus musculus with 70 samples.

How the data were processed

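RNA of mouse forebrain was sequenced on an Illumina HiSeq instrument in 70 libraries of 17 groups, as RiboTag pulldown, as cells sorted by the 7AAD-negative, CD11b-positive, CD45 low or intermediate gate after collagenase digestion and a Percoll gradient, or as bulk input. The labels' design text gives N=3-5 animals per condition, and each library was taken as 1 animal. Values came from the 1 deposited table of RPKM (reads per kilobase of coding length and per 1e6 reads), which the authors made, by the submitters' processing notes, with CASAVA, TopHat2 and featureCounts on mm10, in versions not given in the sources used here. Raw reads were not used, and whether counting kept the strand is not given in the sources used here.

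The table held 43346 genes, of which 27 had symbols turned into dates by a spreadsheet, all restored through their Ensembl identifiers. A further 59 symbols stood under more than 1 identifier and were kept apart, and 37 genes of the mitochondrial chromosome were at 0 in every library. Group and replicate were read from the labels and checked against Xist, Y-linked and cell type markers. Each library's RPKM values moved in steps of a whole read over the coding length plus 1 base. Reads recovered from these steps were whole for 100.0% of genes within 0.01 read and summed to 20.5 to 47.2 M per library, while the RPKM denominators were 49.5 to 119.9 M. Between replicates the reads varied more than counting alone allows, with chi-squared per degree of freedom from 4.14 to 809.97.

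Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with a moderated, trend-adjusted variance (eBayes), a pseudocount of 1 RPKM, genes with a mean of at least 1 RPKM over the libraries of the fit, and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05 with no limit on fold. The 4 groups of the LPS study that came from pulldowns and sorted cells shared a fit, as did the 6 ageing groups, and the APP/PS1 and TauP301L groups for their difference. In the LPS study this gave sorted and pulldown libraries 1 shared spread. Yet log2 values of replicates correlated at 0.81 to 0.90 among sorted and at 0.96 to 0.99 among pulldown libraries. Pulldown against input, Poly(I:C), APP/PS1 and TauP301L were each fitted on their own groups. In all 19 comparisons were made, 3 of them differences of effects. Replicate numbers were not used to pair libraries. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

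Gene groups were 26 lists fixed before the values were read. They covered homeostatic and disease-associated microglia, lipid and lipoprotein handling, interferon response, inflammatory cytokines and NF-kB targets, MHC and antigen processing, complement, immediate early and heat shock genes, lysosome and phagocytosis, cell cycle, glycolysis, cytosolic ribosomal proteins, oxidative phosphorylation, X-linked and Y-linked genes. The other lists held markers of neurons, astrocytes, oligodendrocytes and their precursors, endothelial, mural, ependymal and choroid plexus, erythroid and lymphoid cells, perivascular macrophages, and monocytes and neutrophils. Each list of at least 5 tested members was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. Members called over all genes and called when p was adjusted over the list alone were counted. Overlaps were tested with a one-sided Fisher exact test among the genes tested in both comparisons.

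Genes were named by rule. For each comparison these were the 8 highest and 8 lowest called genes whose library values did not overlap between groups. Differences of effects lacked that condition. Up to 3 genes of each list were added by smallest p, called or not. Apoe, Trem2, Tyrobp, Cx3cr1, P2ry12 and Tmem119 were always kept. Added were App and Prnp for APP/PS1, Mapt for TauP301L, and Xist and Ddx3y between the sexes. Predicted and clone-named genes and pseudogenes were left out. The rule gave 1684 pairs of gene and comparison, of which 234 are printed and 1450 are kept in the result tables.

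The steps were tested on simulated data, drawn from negative binomial distributions around each control group's profile and spread, with 67 genes changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. Of the 2-fold changes 88.1% were recovered for pulldown against input, 37.3% for LPS by pulldown, 77.6% for Poly(I:C), 92.5% for APP/PS1, 86.6% for TauP301L and 95.5% for 24 against 3 months in females, with 5 to 8 false calls each. Changes of 1.5-fold were recovered for 25.4% in the LPS pulldowns to 80.6% in female ageing.

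Alternatives fixed before the data were examined were a pseudocount of 0.1 RPKM, no filter on low values, a mean of at least 5 RPKM, median-of-ratios scaling, a fold change of at least 2, a replicate block, a fit of only the compared groups, a carry-over covariate (the mean log2 value of 3 marker lists, for neurons, astrocytes and oligodendrocytes) and leaving out each library in turn. Added after values were seen were limma voom on the recovered reads and a fit without saline RiboTag replicates 3 and 4. Libraries were also regrouped at random up to 100 times per comparison, for differences of effects within each part of the study and after the effect common to both parts was taken out, which was chosen after values were seen, and 120 groups of values were searched for outlying libraries.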

Results

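The series measured RNA of mouse forebrain microglia by sequencing in 70 libraries that fell into 17 groups. In RiboTag mice, Cre recombinase driven from the Cx3cr1 locus switches on an epitope-tagged ribosomal protein, RPL22, so that ribosome-bound RNA of the tagged cells can be pulled down from whole tissue without dissociating it. The LPS study held saline RiboTag pulldowns (n = 4), LPS RiboTag pulldowns (n = 3, replicates 1, 3 and 4), microglia sorted after saline (n = 3) or LPS (n = 3), and the bulk forebrain input of the pulldowns (n = 4). LPS, a bacterial endotoxin, and Poly(I:C), a synthetic double-stranded RNA that mimics a viral infection, were given into the peritoneum 24 hours before harvest. The Poly(I:C) study had its own saline controls (n = 3 per group). APP/PS1 mice, which form amyloid plaques, and their controls (n = 5 per group) and mice given an adeno-associated virus carrying TauP301L, a mutant human tau, or GFP (n = 5 per group) were 9 to 10 months old. The ageing study held females at 3 (n = 5), 12 (n = 5) and 24 months (n = 4, replicates 1, 2, 3 and 5) and males at 3 (n = 5), 12 (n = 4) and 24 months (n = 4). The labels give no sex for the other studies. In all of their libraries Xist was at most 0.182 RPKM, against at least 14.3 in females of the ageing study. The Y-linked gene Ddx3y was at least 3.3 RPKM there, against at most 0.0309 in those females, so these libraries read as male.

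The reads in genes, recovered from the steps of the deposited RPKM values, ranged from 20.5 to 47.2 M (1e6 reads) per library. They were 31.5 to 47.2 M in saline RiboTag, 36.8 to 46.1 M in LPS RiboTag, 28.6 to 30.9 M in saline sorted, 31.2 to 46.5 M in LPS sorted and 20.5 to 25.7 M in input libraries. The Poly(I:C) study held 27.3 to 41.2 M in its controls and 37.3 to 39.5 M after treatment. APP/PS1 libraries held 26.7 to 33.6 M and their controls 28.1 to 35.7 M, TauP301L libraries 22.1 to 32.8 M and GFP libraries 22.0 to 28.1 M. Across the ageing groups the range was 20.9 to 34.5 M. Levels below are mean RPKM ± SD over libraries, and log2 fold changes are given ± the standard error of limma's model on log2(RPKM + 1), a scale that understates changes of weakly expressed genes. Adjusted p values are limma's. Coordinates are those of the deposited table, on mm10.

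To learn how far the pulldown enriched microglial RNA, saline RiboTag libraries were compared with the input, both n = 4. Tmem119 (ENSMUSG00000054675, chromosome 5, 113793729 to 113800516), a surface marker of microglia, stood at 85.4 ± 45.4 RPKM in the pulldown and 1.16 ± 0.202 in the input, a log2 fold change of 5.16 ± 0.34 (adjusted p = 3.73e-05). C1qb, a chain of complement C1q, rose by 5.96 ± 0.35, and the lysosomal protease gene Ctss by 5.95 ± 0.37. P2ry12, the purinergic receptor of resting microglia, rose by 5.16 ± 0.36, the fractalkine receptor gene Cx3cr1 by 4.42 ± 0.36, Tyrobp, the adaptor of the lipid receptor TREM2, by 4.95 ± 0.32 and Trem2 itself by 3.12 ± 0.27. Of 18 tested genes of the homeostatic microglia list, 17 were higher (17 adjusted over the list alone), with a median of 4.42 and a camera adjusted p of 1.58e-05, which was adjusted p = 0.659 with an estimated correlation. The lysosome and phagocytosis list had 19 of 20 members higher (19 adjusted over the list alone, camera adjusted p = 0.000151, adjusted p = 0.659 with an estimated correlation). All 12 tested genes of MHC and antigen processing were higher (12 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.659 with an estimated correlation), among them Cd74, the MHC class II invariant chain, at 4.78 ± 0.32, although reads of related H2 genes may be shared.

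Genes of other brain cells were depleted. Snap25, a synaptic vesicle fusion protein of neurons, fell from 294 ± 22.5 RPKM in the input to 87.3 ± 20.4 in the pulldown, a change of -1.77 ± 0.19 (adjusted p = 8.63e-05). Ttr, the transthyretin gene of the choroid plexus, changed by -2.20 ± 0.26, Slc1a2, a glutamate transporter of astrocytes, by -1.44 ± 0.15 and the myelin gene Mal by -1.45 ± 0.15. Of 15 tested neuronal markers 14 were lower (14 adjusted over the list alone), with a median of -0.93 and a camera adjusted p of 7.13e-15, or adjusted p = 0.158 with an estimated correlation. The astrocyte list had 10 of 13 lower (10 adjusted over the list alone, camera adjusted p = 2.9e-10, adjusted p = 0.248 with an estimated correlation) and the oligodendrocyte list 9 of 12 (9 adjusted over the list alone, camera adjusted p = 2.23e-07, adjusted p = 0.436 with an estimated correlation). All 6 tested markers of perivascular macrophages were higher (6 adjusted over the list alone, camera adjusted p = 0.0517), including the mannose receptor gene Mrc1 at 2.81 ± 0.34 and the chemokine gene Pf4 at 2.75 ± 0.35. Of 5 erythroid genes 4 were higher (4 adjusted over the list alone), with Hbb-bs at 3.12 ± 0.61. Mural cell markers were lower for 3 of 4 members, ependymal and choroid plexus markers for 3 of 4 and endothelial markers for 1 of 4, with 1 higher (3, 3 and 1 lower adjusted over the list alone). Apoe, the lipid carrier that astrocytes also make, differed by 0.86 ± 0.35 with adjusted p = 0.0535 and was not called. Of 12780 genes tested, 8602 were called, 7256 higher and 1346 lower, and the median of all genes was 0.41. Median-of-ratios scaling moved that median to 0.02 and the split to 3437 higher and 3505 lower, and turned the median of the cytosolic ribosomal protein list from 0.37 to -0.11.

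The design text names a comparison of pulldown with enzymatic digestion and cell sorting, and under saline the contrast covered 4 RiboTag and 3 sorted libraries. The calprotectin subunit genes S100a8 and S100a9, abundant in neutrophils, stood at 4763 ± 2680.4 and 4791 ± 2814 RPKM in sorted cells and at 3.59 ± 3.96 and 3.94 ± 3.67 in the pulldown. The neutrophil granule genes Ngp and Camp differed by -9.07 ± 0.39 and -7.63 ± 0.57, and the interleukin-1 beta gene Il1b by -5.10 ± 0.22. Of 16 tested markers of monocytes and neutrophils 15 were lower in the pulldown (15 adjusted over the list alone, median -5.79, camera adjusted p = 9.63e-14, adjusted p = 0.05 with an estimated correlation). Immediate early and heat shock genes were lower for 20 of 25 members (22 adjusted over the list alone, median -2.20, camera adjusted p = 1.25e-12, adjusted p = 0.05 with an estimated correlation), with Jun, a subunit of the AP-1 transcription factor, at -4.25 ± 0.25, the stress-induced factor gene Atf3 at -3.62 ± 0.24 and Zfp36, which marks inflammatory mRNAs for decay, at -5.36 ± 0.33. The inflammatory cytokine and NF-kB target list was lower for 19 of 28 members (20 adjusted over the list alone, camera adjusted p = 5.84e-10, adjusted p = 0.05 with an estimated correlation), and those libraries were the ones with the neutrophil transcripts.

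Markers of other brain cells were higher in the pulldown than in sorted cells. All 14 tested neuronal markers were higher (14 adjusted over the list alone, median 3.37, camera adjusted p = 2.99e-11, adjusted p = 0.05 with an estimated correlation), such as Snap25 at 5.57 ± 0.25 and the dendritic protein gene Map2 at 4.16 ± 0.15. The oligodendrocyte list had 10 of 12 higher (10 adjusted over the list alone) and the astrocyte list 8 of 9 (8 adjusted over the list alone), with Slc1a2 at 4.69 ± 0.23. Homeostatic microglial genes were lower in the pulldown for 14 of 18 members (15 adjusted over the list alone, median -1.81, camera adjusted p = 8.4e-08, adjusted p = 0.313 with an estimated correlation), including P2ry12 at -1.82 ± 0.39 and Cx3cr1 at -2.10 ± 0.38. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699166) was higher in the pulldown, 38.6 ± 19.9 against 8.93 ± 4.73 RPKM (1.99 ± 0.50, adjusted p = 0.0072). Of 7 perivascular macrophage markers 4 were higher and 1 was lower (4 and 1 adjusted over the list alone), with Pf4 at 3.00 ± 0.37 and the scavenger receptor gene Stab1 at -1.90 ± 0.28. All 5 erythroid genes were higher (5 adjusted over the list alone, camera adjusted p = 0.0113, adjusted p = 0.334 with an estimated correlation), with Hbb-bs at 4.19 ± 0.54. Of 13908 genes, 5555 were called, 3861 higher and 1694 lower in the pulldown, around a median of all genes of 0.25, which scaling moved to 0.11.

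For the acute response to LPS by pulldown, 3 LPS and 4 saline RiboTag libraries were compared. Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715676), an acute-phase serum amyloid A gene, rose from 0.0801 ± 0.0930 to 136 ± 50.2 RPKM (6.93 ± 0.31, adjusted p = 8.8e-07). The chemokine gene Ccl5 rose by 2.94 ± 0.24 and Il1b by 2.22 ± 0.22. These 3 were the named genes, out of 28 called, whose calls held without each of the 7 libraries in turn. The monocyte-attracting chemokine gene Ccl12 at 5.05 ± 0.59, the fatty acid receptor gene Gpr84 at 3.45 ± 0.39 and the interferon-induced antiviral gene Ifitm3 at 3.15 ± 0.37 passed the test (adjusted p = 0.00436 for each), and without LPS replicate 4 each had adjusted p = 0.0538. The inflammatory list had 11 of 28 members higher (18 adjusted over the list alone), with a median of 1.38 and a camera adjusted p of 1.23e-22, or adjusted p = 0.00637 with an estimated correlation. That count became 6, 5 and 5 without saline replicate 1, 3 or 4, and 5, 5 and 3 without LPS replicate 1, 3 or 4.

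Cytosolic ribosomal protein genes, some with pseudogenes that share their reads, rose for 17 of 40 members (39 adjusted over the list alone, median 1.46, camera adjusted p = 2.07e-43, adjusted p = 0.0364 with an estimated correlation). At most 1 of them was called without saline replicate 3 or 4 or LPS replicate 1, 3 or 4. The interferon response list had 2 of 28 higher (13 adjusted over the list alone, median 1.07, camera adjusted p = 1.92e-12, adjusted p = 0.0792 with an estimated correlation) and the cell cycle list 3 of 12 (6 adjusted over the list alone, camera adjusted p = 1.13e-06, adjusted p = 0.0364 with an estimated correlation). None of the 18 homeostatic genes was called by limma, 4 reached an unadjusted p under 0.05, and their median of 0.15 became -0.20 with scaling. Apoe had 0.40 ± 0.50 (adjusted p = 1). Oligodendrocyte markers moved with the treatment, with a median of -0.30 (camera adjusted p = 8.32e-08, adjusted p = 0.0364 with an estimated correlation), and so did perivascular macrophage markers, with a median of 1.23 and 2 of 7 higher (3 adjusted over the list alone, camera adjusted p = 1.76e-05, adjusted p = 0.116 with an estimated correlation). These were the sialic acid receptor gene Siglec1 at 1.28 ± 0.20 and Cbr2 at 1.76 ± 0.34 (adjusted p = 0.0155 and 0.0321). Without saline replicate 3 or 4 or LPS replicate 3 or 4 Siglec1 had adjusted p = 0.0722, 0.0589, 0.125 and 0.122 and Cbr2 0.106, 0.116, 0.177 and 0.186, and Cbr2 had 0.0938 without LPS replicate 1. Scaling also ended both calls (adjusted p = 0.105 for Siglec1 and 0.0713 for Cbr2) and left the median of that list at 0.91. The mean log2 level of the homeostatic list spread from 5.21 to 6.68 among the 4 saline libraries, against 5.87 to 6.29 after LPS. In all, 189 of 13908 genes were called, 185 higher and 4 lower, around a median of all genes of 0.12, which scaling moved to -0.12 with 47 calls. A fit of only these 7 libraries, without the sorted ones, gave 1720 calls, a replicate block 48 and limma voom 79. The count was 115, 31 and 30 without saline replicate 1, 3 or 4, 43, 18 and 3 without LPS replicate 1, 3 or 4, and 12 without saline replicates 3 and 4 together.

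In sorted cells the LPS response was measured in 3 LPS and 3 saline libraries. Saa3 rose by 6.14 ± 0.33 (adjusted p = 7.41e-06), Ccl12 by 5.72 ± 0.63, the chemokine genes Ccl7 and Ccl2 by 4.96 ± 0.50 and 4.19 ± 0.60, and Cst7, a cysteine protease inhibitor, by 4.40 ± 0.38. The scavenger receptor gene Msr1 rose by 4.43 ± 0.35, Ch25h, which makes 25-hydroxycholesterol, by 3.90 ± 0.29 and the ferritin heavy chain gene Fth1 by 2.23 ± 0.29. Of 28 inflammatory genes 19 were higher (23 adjusted over the list alone, median 2.35, camera adjusted p = 5.42e-16, adjusted p = 0.0207 with an estimated correlation). The immediate early and heat shock list had 10 of 25 higher (16 adjusted over the list alone, camera adjusted p = 1.12e-08, adjusted p = 0.208 with an estimated correlation). Homeostatic genes had a median of -0.34, with 2 of 18 lower (5 adjusted over the list alone, camera adjusted p = 0.00284, adjusted p = 0.549 with an estimated correlation). The lysosome list had 3 of 21 higher and a median of 0.30, which became -0.02 with scaling. Of 16 monocyte and neutrophil markers 4 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0965), together 3 without saline sorted replicate 1. The chemokine receptor gene Cxcr2 had 2.15 ± 0.29, while mean levels went both ways, from 4763 to 12760.0 RPKM for S100a8 and from 256 to 112 for Camp. Klrd1, a receptor of natural killer cells, had -2.45 ± 0.46, and 1 of 3 lymphocyte markers was lower. In all 1227 genes were called, 975 higher and 252 lower, or 558 and 496 with scaling. A fit of only these 6 libraries, without the pulldowns, left 72, among them the 9 genes given here as higher but not Klrd1 (adjusted p = 0.191), and a replicate block 767. Of the genes higher after LPS in pulldowns, 116 were also higher in sorted cells by the shared fit, more than expected by chance (one-sided Fisher exact p = 1.43e-87).

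LPS responses of both methods were compared by an interaction term, neutrophil RNA in sorted cells not told apart. Steap4, an inflammation-induced metalloreductase, responded by 0.18 in pulldowns and 3.74 in sorted cells, a difference of -3.56 ± 0.33 (adjusted p = 0.00316). Of 13 named genes called, only it kept its call without each of the 13 libraries in turn. No homeostatic gene out of 18 was called by limma, with 0 at an unadjusted p under 0.05 and a median difference of 0.58 (camera adjusted p = 0.00277, adjusted p = 0.808 with an estimated correlation). None of the 28 inflammatory genes was called, 7 had an unadjusted p under 0.05, and the median difference was -0.65 (camera adjusted p = 0.00277, adjusted p = 0.808 with an estimated correlation). The interaction called 36 genes, 14 higher and 22 lower in pulldowns, and other groupings of the same libraries, with the LPS effect common to both methods taken out, called up to 148. With a replicate block it called 1. Leaving out 1 library gave 98, 131 or 103 for saline sorted replicate 1, 2 or 3, 9 for saline RiboTag replicate 1, 2 or 3, 15 for replicate 4, 92 for LPS sorted replicate 1 or 2, 180 for replicate 3, and 1, 3 or 2 for LPS RiboTag replicate 1, 3 or 4.

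Poly(I:C) was compared with its own saline controls, 3 libraries each. Ccl12 (ENSMUSG00000035352, chromosome 11, 82101845 to 82103400) rose from 2.52 ± 0.281 to 174 ± 50.0 RPKM (5.60 ± 0.21, adjusted p = 1.53e-05), Ifitm3 by 4.83 ± 0.21, and the viral tethering factor gene Bst2 by 4.37 ± 0.22. All 29 tested genes of the interferon response were higher (29 adjusted over the list alone, median 2.01, camera adjusted p = 5.48e-53, adjusted p = 0.069 with an estimated correlation). MHC and antigen processing genes rose for 9 of 13 members (9 adjusted over the list alone, camera adjusted p = 7.54e-09, adjusted p = 0.202 with an estimated correlation), such as H2-K1 at 2.43 ± 0.19 and the immunoproteasome gene Psmb8 at 1.92 ± 0.13. Of 12 complement genes 8 rose (9 adjusted over the list alone, camera adjusted p = 2.86e-10, adjusted p = 0.0821 with an estimated correlation), with the C5a receptor gene C5ar1 at 1.55 ± 0.14. The replication licensing genes Mcm2 and Mcm6 rose by 1.63 ± 0.10 and 1.77 ± 0.14, and 6 of 8 cell cycle genes were higher (7 adjusted over the list alone, camera adjusted p = 5.63e-11, adjusted p = 0.0866 with an estimated correlation). Ribosomal protein genes rose for 32 of 39 members (36 adjusted over the list alone, camera adjusted p = 1.55e-32, adjusted p = 0.109 with an estimated correlation), a count that was 21 without saline replicate 3.

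Btg2, an antiproliferative immediate early gene, fell after Poly(I:C) by -1.21 ± 0.18. Olfml3, an extracellular protein of microglia, rose by 2.00 ± 0.14 and Tmem119 by 1.19 ± 0.14, and 7 of 18 homeostatic genes were higher (10 adjusted over the list alone, camera adjusted p = 3.85e-05, adjusted p = 0.32 with an estimated correlation). That count was 3 without saline replicate 1, 2 or 3 and 4 without Poly(I:C) replicate 1. The lysosome list had 13 of 20 higher (15 adjusted over the list alone, median 0.70, camera adjusted p = 9.38e-14, adjusted p = 0.0866 with an estimated correlation), such as Ctsz at 1.91 ± 0.24, and 8, 6 and 6 without saline replicate 1, 2 or 3. Disease-associated genes were higher for 8 of 21 (9 adjusted over the list alone, median 0.36, camera adjusted p = 4.24e-06, adjusted p = 0.308 with an estimated correlation), with Spp1 at 1.03 ± 0.14, and 4, 4 and 5 without saline replicate 1, 2 or 3 and 5 without Poly(I:C) replicate 1. Apoe differed by -0.04 ± 0.13 (adjusted p = 0.935). The neuronal list had a median of -0.09 with no member called by limma and 0 of 15 at an unadjusted p under 0.05. The count was 878 of 13505 genes, 847 higher and 31 lower, and it was 550 and 538 without saline replicate 2 or 3. Genes higher after LPS in pulldowns and after Poly(I:C) numbered 135, against 10.7 expected (one-sided Fisher exact p = 3.18e-138), and across genes, which are not independent replicates, the correlation of both sets of log2 fold changes was 0.76.

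Amyloid was examined in APP/PS1 mice against controls, 5 libraries each. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944) rose from 1.59 ± 0.290 to 47.5 ± 15.8 RPKM (4.16 ± 0.21, adjusted p = 1.84e-06). The chemokine genes Ccl3 and Ccl4 rose by 2.78 ± 0.25 and 1.27 ± 0.18, Itgax, the integrin alpha X chain, by 1.25 ± 0.11, the glycoprotein gene Gpnmb by 1.13 ± 0.10 and Lpl, the lipoprotein lipase gene, by 1.02 ± 0.10. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699166) rose from 63.5 ± 3.15 to 121 ± 22.0 RPKM (0.90 ± 0.11, adjusted p = 0.00246). Of 25 tested genes of the disease-associated microglia list, a set known from plaque-associated microglia, 18 were higher (22 adjusted over the list alone), with a median of 0.65 and a camera adjusted p of 3.11e-45, or adjusted p = 0.0376 with an estimated correlation. The lysosome and phagocytosis list had 9 of 20 higher (16 adjusted over the list alone, camera adjusted p = 1.43e-25, adjusted p = 0.0714 with an estimated correlation), with the macrosialin gene Cd68 at 0.73 ± 0.08 and the cathepsin gene Ctsb at 0.60 ± 0.08. Tyrobp rose by 0.65 ± 0.10, and Trem2 had 0.47 ± 0.11 with adjusted p = 0.0588. Prnp (ENSMUSG00000079037, chromosome 2, 131909928 to 131938429), the prion protein gene, rose by 1.90 ± 0.05 and App, the amyloid precursor gene, by 0.46 ± 0.06. Reads of a human or mutant transgene were not told apart from the mouse gene in the table. Gfap, an intermediate filament of astrocytes, rose by 0.47 ± 0.06, 1 of 13 astrocyte markers.

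No homeostatic gene out of 18 was called by limma in APP/PS1 (1 at an unadjusted p under 0.05), and their median was 0.06. The interferon response list had a median of 0.21, none of 17 called, 8 at an unadjusted p under 0.05 and 6 adjusted over the list alone (camera adjusted p = 9.49e-10, adjusted p = 0.16 with an estimated correlation). Inflammatory genes were higher for 3 of 13 members (6 adjusted over the list alone, camera adjusted p = 1.47e-07, adjusted p = 0.0376 with an estimated correlation). Among the lower genes, Arpp21, a phosphoprotein of striatal neurons, had -0.46 ± 0.04 and the enkephalin precursor gene Penk -0.33 ± 0.05. The comparison called 189 of 14431 genes, 75 higher and 114 lower, 11 of them higher at least 2-fold, and scaling turned the split to 103 higher and 43 lower. It called 47 with a replicate block, 85 without a filter on low values and 423 with limma voom. Without control replicate 1, 2, 3 or 4 the count was 104, 106, 89 or 64, and without APP/PS1 replicate 1, 2, 3 or 5 it was 62, 93, 90 or 91.

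TauP301L was compared with GFP, 5 libraries each. Apoe rose from 24.0 ± 5.92 to 88.2 ± 9.34 RPKM (1.86 ± 0.15, adjusted p = 0.000113). Ccl3 rose by 1.92 ± 0.11, Spp1, the osteopontin gene, by 1.77 ± 0.13, Gpnmb by 1.57 ± 0.11, Cst7 by 1.51 ± 0.15, the receptor tyrosine kinase gene Axl by 1.03 ± 0.08 and the lysozyme gene Lyz2, whose reads may be shared with Lyz1, by 1.33 ± 0.19. Clec7a, a receptor for beta-glucan, is in the table under 2 gene identifiers and rose by 1.95 ± 0.14 under the one with the higher level. Of 24 disease-associated microglia genes 16 were higher (22 adjusted over the list alone, median 0.70, camera adjusted p = 3.63e-34, adjusted p = 0.0696 with an estimated correlation). The lysosome list had 9 of 20 higher (16 adjusted over the list alone, camera adjusted p = 7.97e-19, adjusted p = 0.137 with an estimated correlation), or 5 without TauP301L replicate 3, with Ctsz, a cathepsin, at 0.85 ± 0.11. The anaphylatoxin receptor gene C3ar1 rose by 0.60 ± 0.09, Atf3 by 0.80 ± 0.10 and the astrocytic Gfap by 0.61 ± 0.09.

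In the TauP301L pulldowns Slc17a7, the vesicular glutamate transporter gene of cortical neurons, fell by 0.46 ± 0.07 and Camk2a, a synaptic kinase, by 0.37 ± 0.05. Of 15 neuronal markers 4 were lower (7 adjusted over the list alone, median -0.16, camera adjusted p = 6.34e-07, adjusted p = 0.137 with an estimated correlation), or 2 without GFP replicate 1 or TauP301L replicate 1, 3 or 5. No homeostatic gene out of 18 was called by limma (5 at an unadjusted p under 0.05, median 0.06). Mapt, the endogenous tau gene, had -0.05 ± 0.05 (adjusted p = 0.662). Trem2 at 0.43 ± 0.09 and Tyrobp at 0.51 ± 0.10 had adjusted p = 0.0492 and 0.0402, and of the 10 fits that each left out 1 library only that without GFP replicate 5 kept both calls (0.00286 and 0.0101). The others gave adjusted p of 0.0698 to 0.124 for Trem2 and 0.05 to 0.104 for Tyrobp, both highest without TauP301L replicate 3. The comparison called 161 of 12864 genes, 90 higher and 71 lower, or 285 with scaling and 92 with the mean level of neuronal, astrocytic and oligodendrocytic markers as a covariate. It called 22 with a replicate block, 81 without a filter and 687 with limma voom. The count was 67, 86, 76 and 275 without GFP replicate 1, 2, 3 or 5, and 68, 92, 55 and 70 without TauP301L replicate 1, 2, 3 or 5.

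APP/PS1 and TauP301L effects, each against its own controls, were compared over 20 libraries. Cst7 rose more in APP/PS1, by 2.65 ± 0.28 (adjusted p = 5.83e-05). So did Prnp by 2.00 ± 0.11 and App by 0.59 ± 0.08, transgene reads not told apart. Slc17a7 differed by 0.60 ± 0.09, the cortical neuron factor gene Fezf2 by 0.67 ± 0.11 and the NADPH oxidase gene Cybb by -0.56 ± 0.08. The difference in Apoe was -0.96 ± 0.19 (adjusted p = 0.0247), with adjusted p = 0.0561 without TauP301L replicate 3 and 0.0506 without control replicate 3. Of 25 disease-associated microglia genes 2 differed upward in APP/PS1 and 1 downward (2 and 4 adjusted over the list alone), with a median of -0.10. Neuronal markers differed upward for 3 of 15 (5 upward and 1 downward adjusted over the list alone, camera adjusted p = 7.19e-06, adjusted p = 0.238 with an estimated correlation). In all 117 of 13810 genes differed, 47 upward and 70 downward, or 191 and 54 with scaling. A replicate block gave 44 and limma voom 365. The count was 51, 47 and 55 without control replicate 2, 3 or 4, 38, 68, 56 and 50 without APP/PS1 replicate 1, 2, 4 or 5, 70 and 57 without GFP replicate 2 or 3, and 70, 46 and 178 without TauP301L replicate 1, 3 or 4.

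Ageing was measured in each sex, and 24 against 3 months in females set 4 libraries against 5. Spp1 (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050) rose to 19.4 ± 3.44 RPKM (3.66 ± 0.14, adjusted p = 2.63e-15), Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355) by 3.14 ± 0.13 and Cst7 by 2.94 ± 0.16. Apoe rose from 33.1 ± 3.94 to 202 ± 25.6 RPKM (2.57 ± 0.11, adjusted p = 6.22e-15). Lyz2 rose by 2.24 ± 0.09, the tetraspanin gene Cd63 by 1.69 ± 0.07, Clec7a (ENSMUSG00000079293, chromosome 6, 129461591 to 129472777) by 2.20 ± 0.08, Axl by 1.12 ± 0.05, Tyrobp by 1.32 ± 0.10 and Trem2 by 0.91 ± 0.11. Of 23 disease-associated microglia genes 21 were higher (21 adjusted over the list alone, median 1.15, camera adjusted p = 3.64e-36, adjusted p = 0.00189 with an estimated correlation). All 20 lysosomal genes were higher (20 adjusted over the list alone, camera adjusted p = 1.7e-27, adjusted p = 0.0116 with an estimated correlation), with Ctsb at 1.15 ± 0.07. Interferon response genes rose for 12 of 13 (12 adjusted over the list alone, adjusted p = 0.0225 with an estimated correlation), with Bst2 at 1.06 ± 0.11. MHC and antigen processing rose for 9 of 13 (9 adjusted over the list alone, adjusted p = 0.045 with an estimated correlation), with H2-D1 at 1.64 ± 0.10 and B2m, the shared light chain of MHC class I, at 1.49 ± 0.10. Lipid and lipoprotein handling rose for 12 of 17 (13 adjusted over the list alone, adjusted p = 0.0194 with an estimated correlation), including Lpl at 0.88 ± 0.06.

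Ribosomal protein genes rose in old females for 38 of 39 members (38 adjusted over the list alone, median 0.49, adjusted p = 0.0269 with an estimated correlation), complement genes for 7 of 12 (7 adjusted over the list alone, adjusted p = 0.045 with an estimated correlation) with C4b at 1.30 ± 0.07, and inflammatory genes for 7 of 10 (7 adjusted over the list alone, adjusted p = 0.0052 with an estimated correlation). Homeostatic genes were higher for 5 of 18 (8 adjusted over the list alone, median 0.18), or 8 without 24-month replicate 3. The haemoglobin gene Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), whose paralogs may share reads, fell from 8.54 ± 6.80 to 0.253 ± 0.126 RPKM (-2.56 ± 0.43), and 4 of 5 erythroid genes were lower (4 adjusted over the list alone, adjusted p = 0.0365 with an estimated correlation). Oxidative phosphorylation genes rose for 11 of 27 (16 adjusted over the list alone), or 7 without 3-month replicate 1 or 24-month replicate 3, and glycolytic genes for 9 of 15 (10 adjusted over the list alone), with Gapdh at 0.59 ± 0.09. Markers of other cells moved as well. The oligodendrocyte list had 8 of 13 higher (11 adjusted over the list alone, camera adjusted p = 3.09e-05, adjusted p = 0.101 with an estimated correlation), with the myelin gene Mobp at 0.55 ± 0.06. Gfap rose by 1.02 ± 0.05 and the immunoglobulin heavy chain gene Ighm by 0.59 ± 0.07, and 2 of 15 neuronal markers were lower (2 adjusted over the list alone). Perivascular macrophage markers were higher for 3 of 7 (4 adjusted over the list alone), with Cbr2 at 0.66 ± 0.13. Gabra2, a GABA receptor subunit, had -0.55 ± 0.05 and Homer1, a postsynaptic scaffold, -0.54 ± 0.08. In all 2853 of 14198 genes were called, 2369 higher and 484 lower, or 1552 and 1322 with scaling, and 1257 with the carry-over covariate.

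At 12 against 3 months, females (n = 5 each) showed smaller changes. The lectin gene Cd209a rose by 1.14 ± 0.12 (adjusted p = 8.15e-06), Ccl3 by 0.84 ± 0.12, Lyz2 by 0.53 ± 0.09, B2m by 0.49 ± 0.09 and Apoe by 0.48 ± 0.10 (adjusted p = 0.0123). The disease-associated list had 11 of 23 higher (14 adjusted over the list alone, camera adjusted p = 3.37e-08, adjusted p = 0.264 with an estimated correlation), and 6, 7 and 6 without 3-month replicate 2 or 12-month replicate 1 or 2. Hbb-bs fell by 2.51 ± 0.40 and 4 of 5 erythroid genes were lower (5 adjusted over the list alone, camera adjusted p = 4.8e-11, adjusted p = 0.0218 with an estimated correlation). Sox11, a factor of immature neurons, had -0.29 ± 0.04, and the neuronal list had a median of 0.04, or -0.01 with scaling. Markers of other cells were called too, the astrocytic S100b and Gfap at 0.30 ± 0.07 and 0.18 ± 0.04, the mural Acta2 at 0.41 ± 0.10 and the perivascular Pf4 at 0.41 ± 0.10 (adjusted p = 0.023, 0.0243, 0.0265 and 0.0338). With the carry-over covariate these had 0.24, 0.17, 0.35 and 0.45 and adjusted p = 0.162, 0.118, 0.165 and 0.0795. Without 3-month replicate 2 or 3 or 12-month replicate 1 or 2 S100b had adjusted p = 0.0735, 0.0539, 0.0731 and 0.0548, and without 3-month replicate 4 or 12-month replicate 3 Gfap had 0.0657 and 0.064. Acta2 had 0.0998, 0.0611 and 0.061 without 3-month replicate 2 or 12-month replicate 1 or 3. Pf4 had 0.0526, 0.11, 0.0573 and 0.05 without 3-month replicate 1, 2, 3 or 5 and 0.0612, 0.0896 and 0.0683 without 12-month replicate 2, 3 or 5. The comparison called 418 genes, 363 higher and 55 lower, which scaling turned to 148 and 171. The carry-over covariate left 52, with B2m at 0.40 and Apoe at 0.39 no longer called (adjusted p = 0.0583 and 0.108). A fit of only these groups gave 107, and one without a filter 229. Without 3-month replicate 2, 3 or 4 the count was 144, 259 or 218, and without 12-month replicate 1, 2, 3 or 4 it was 164, 182, 200 or 808.

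From 12 to 24 months in females, Spp1 rose by 3.14 ± 0.14 (adjusted p = 9.92e-14), Cst7 by 2.56 ± 0.16, Ccl3 by 2.30 ± 0.13, Apoe by 2.09 ± 0.11 and Clec7a by 1.86 ± 0.08. Of 23 disease-associated genes 20 were higher (20 adjusted over the list alone, median 0.91, adjusted p = 0.00012 with an estimated correlation), of 20 lysosomal genes 17 (18 adjusted over the list alone, adjusted p = 0.00408 with an estimated correlation) and of 13 interferon response genes 11 (11 adjusted over the list alone, adjusted p = 0.00495 with an estimated correlation). Markers of other cells rose with them, Gfap by 0.84 ± 0.05, Ighm by 0.38 ± 0.07 and Mobp by 0.36 ± 0.06, which was 1 of 3 called out of 13 oligodendrocyte markers (7 adjusted over the list alone, camera adjusted p = 7.82e-05, adjusted p = 0.15 with an estimated correlation), or 1 called without 12-month replicate 4 or 24-month replicate 2 or 3. Gabra2 had -0.43 ± 0.05. The count was 773, 677 higher and 96 lower, and 505 without 24-month replicate 1.

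In males 4 libraries at 24 months were compared with 5 at 3 months. Ccl3 rose by 2.13 ± 0.13 (adjusted p = 1.53e-11), Cst7 by 1.86 ± 0.16, Spp1 by 1.78 ± 0.14, H2-D1 by 1.86 ± 0.10 and Ccl12 by 1.84 ± 0.14. Apoe rose from 27.5 ± 3.33 to 101 ± 19.0 RPKM (1.83 ± 0.11, adjusted p = 1.53e-11), Lyz2 by 1.65 ± 0.09, Trem2 by 0.97 ± 0.11 and Tyrobp by 1.08 ± 0.10. Of 23 disease-associated genes 19 were higher (20 adjusted over the list alone, median 1.00, camera adjusted p = 8.88e-25, adjusted p = 0.00876 with an estimated correlation). All 20 lysosomal genes (20 adjusted over the list alone, adjusted p = 0.0181 with an estimated correlation), 12 of 13 interferon response genes (12 adjusted over the list alone, adjusted p = 0.0181 with an estimated correlation) and 35 of 39 ribosomal protein genes (37 adjusted over the list alone, adjusted p = 0.0424 with an estimated correlation) were higher. Homeostatic genes were higher for 16 of 18 (16 adjusted over the list alone, median 0.40, camera adjusted p = 3.56e-09, adjusted p = 0.119 with an estimated correlation), with Tmem119 at 0.65 ± 0.10, Cx3cr1 at 0.59 ± 0.08 and P2ry12 at 0.36 ± 0.08. Perivascular macrophage markers were higher with them for 5 of 7 (6 adjusted over the list alone, median 0.27, camera adjusted p = 0.0188, adjusted p = 0.312 with an estimated correlation), or 3 without 3-month replicate 2, with the carbonyl reductase gene Cbr2 at 0.54 ± 0.13.

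Immediate early and heat shock genes went both ways in old males, 7 of 21 lower and 4 higher (7 and 5 adjusted over the list alone). The nuclear receptor gene Nr4a1 had -0.64 ± 0.14, and the growth-promoting factor gene Myc 0.32 ± 0.07. The synaptic gene Arc had -1.15 ± 0.20 and Egr2, an early growth response factor, -0.62 ± 0.16. Neuronal markers were lower for 6 of 15 (7 adjusted over the list alone, median -0.14, camera adjusted p = 9.11e-06, adjusted p = 0.079 with an estimated correlation), with Stmn2, a neuronal growth protein, at -0.34 ± 0.05. Gfap rose by 0.46 ± 0.05 and Ighm by 0.72 ± 0.07, and of 13 oligodendrocyte markers 5 were higher and 1 lower (6 and 1 adjusted over the list alone). Gpr17, a receptor of oligodendrocyte precursors, had -0.49 ± 0.07, and 3 of 5 precursor markers were lower (3 adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.11 with an estimated correlation). The erythroid list, lower in females, had 1 of 5 called, upward, and a median of -0.27. In all 3321 of 14198 genes were called, 2439 higher and 882 lower, or 1946 and 1805 with scaling. A fit of only these groups gave 2073. Genes lower with age in both sexes numbered 209, against 30.1 expected (one-sided Fisher exact p = 1.5e-127), and across genes the correlation of the ageing changes of both sexes was 0.66.

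At 12 months (n = 4) against 3 months (n = 5) in males, Btg2 had -1.67 ± 0.24 (adjusted p = 0.000105), Upk1b, a uroplakin, rose by 1.03 ± 0.09, Cd209a by 0.96 ± 0.13, Ccl12 by 0.90 ± 0.14, Tmem119 by 0.59 ± 0.10, Apoe by 0.69 ± 0.11 and Trem2 by 0.50 ± 0.11. Homeostatic genes were higher for 14 of 18 (15 adjusted over the list alone, camera adjusted p = 1.39e-07, adjusted p = 0.181 with an estimated correlation), or 7 without 12-month replicate 2. Perivascular macrophage markers were higher for 4 of 7 (7 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.181 with an estimated correlation), or 2 without 3-month replicate 2 or 12-month replicate 2, with Pf4 at 0.52 ± 0.11. The disease-associated list had 13 of 23 higher (15 adjusted over the list alone, camera adjusted p = 5.17e-09, adjusted p = 0.181 with an estimated correlation). The count was 1969, 1765 higher and 204 lower, which scaling turned to 645 and 627. It was 672 with the carry-over covariate, 1197 without a filter and 507 with a fit of only these groups, where Trem2 had adjusted p = 0.0508. It was 1035 and 1036 without 3-month replicate 2 or 5 and 825 and 959 without 12-month replicate 2 or 3.

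From 12 to 24 months in males (n = 4 each), Ccl3 rose by 1.55 ± 0.13 (adjusted p = 7.77e-08), Cst7 by 1.54 ± 0.17, Spp1 by 1.40 ± 0.15 and Apoe by 1.14 ± 0.12. The hypoxia-inducible factor gene Hif3a had -0.81 ± 0.19, the serine incorporator gene Serinc2 -0.88 ± 0.10 and Gabra2 -0.61 ± 0.06. Disease-associated genes were higher for 18 of 23 (19 adjusted over the list alone, adjusted p = 0.00422 with an estimated correlation) and interferon response genes for 11 of 13 (12 adjusted over the list alone, adjusted p = 0.00545 with an estimated correlation). Neuronal markers were lower for 7 of 15 (9 adjusted over the list alone, camera adjusted p = 2.07e-05, adjusted p = 0.116 with an estimated correlation), with Camk2a at -0.31 ± 0.07, and 4 without 12-month replicate 2. Gfap rose by 0.36 ± 0.05, while 2 of 13 astrocyte markers were lower (8 adjusted over the list alone). The count was 1382, 560 higher and 822 lower, or 806 and 723 with scaling, and 804, 881 and 862 without 12-month replicate 2 or 24-month replicate 1 or 5. The carry-over covariate gave 621.

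Females and males were compared at each age. At 3 months (n = 5 each), Xist (ENSMUSG00000086503, chromosome X, 103460375 to 103483217), the RNA that silences an X chromosome, was higher in females by 3.95 ± 0.05 (adjusted p = 6.22e-28), and Tsix, which lies antisense to Xist and whose reads cannot be assigned to a strand from the sources used here, by 2.08 ± 0.06. The Y-linked helicase gene Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629) was at 0.00129 ± 0.00176 RPKM in females and 8.11 ± 0.920 in males. Of 5 X-inactivation and escape genes 4 were higher (5 adjusted over the list alone, adjusted p = 4.38e-09 with an estimated correlation) and both Y-linked genes tested were lower. Apoe differed by 0.26 ± 0.10 (adjusted p = 0.317), and of 23 disease-associated genes limma called none, with 5 at an unadjusted p under 0.05. The count was 41 of 14198, 31 higher in females and 10 lower, and 96, 24 and 24 without female replicate 1 or 3 or male replicate 5. It was 16 with a fit of only these groups and 85 with limma voom. At 12 months (females n = 5, males n = 4) Xist differed by 4.19 ± 0.05, the microtubule-binding gene Mid1 by 1.09 ± 0.19, Apoe by 0.05 ± 0.11 (adjusted p = 0.921) and Ddx3y by -3.12 ± 0.06. All 5 X-linked list genes were higher (5 adjusted over the list alone, adjusted p = 2.64e-10 with an estimated correlation). The 12-month count was 82, and 47, 47 and 54 without female replicate 2, 4 or 5, and 53, 40 and 42 without male replicate 1, 2 or 3. Limma voom gave 141.

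At 24 months, with 4 libraries per sex, female pulldowns had more of the disease-associated transcripts. Spp1 was at 19.4 ± 3.44 RPKM in females and 4.83 ± 1.83 in males (1.84 ± 0.15, adjusted p = 1.07e-08), and Apoe at 202 ± 25.6 and 101 ± 19.0 (1.00 ± 0.12, adjusted p = 6.18e-06). Cst7 was higher by 1.10 ± 0.17, Ccl3 by 0.90 ± 0.13, Clec7a by 0.89 ± 0.08, Lyz2 by 0.76 ± 0.10, Lpl by 0.51 ± 0.06 and Axl by 0.30 ± 0.06. Of 23 disease-associated genes 8 were higher (18 adjusted over the list alone, median 0.29, camera adjusted p = 2.13e-22, adjusted p = 0.0122 with an estimated correlation). Astrocyte markers moved with them, 1 of 13 called (8 adjusted over the list alone, median 0.15, camera adjusted p = 1.19e-06, adjusted p = 0.0206 with an estimated correlation), with Gfap at 0.46 ± 0.05, and so did 2 of 13 oligodendrocyte markers (median 0.22, camera adjusted p = 0.000233, adjusted p = 0.35 with an estimated correlation). The homeostatic list had a median of -0.08, and Gpr34, a receptor of that list, was higher by 0.43 ± 0.08. Xist differed by 4.14 ± 0.05 and Ddx3y by -3.25 ± 0.06. The count was 116, 90 higher in females and 26 lower, 66, 64 and 76 without female replicate 1, 2 or 3, 74 and 59 without male replicate 4 or 5, and 31 with the carry-over covariate. A fit of only these groups gave 68 and limma voom 234.

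The change from 3 to 24 months was tested for a difference between the sexes. Spp1 rose by 3.66 in females and 1.78 in males, a difference of 1.88 ± 0.20 (adjusted p = 2.57e-05). Clec7a differed by 0.90 ± 0.11 (adjusted p = 0.00011), and Gfap rose by 1.02 and 0.46 (adjusted p = 4.17e-05). These 3 kept their calls without each of the 18 libraries in turn. The difference for Apoe was 0.74 ± 0.15 with adjusted p = 0.0547 and was not called. Of 23 disease-associated genes 2 differed (9 adjusted over the list alone, median 0.22, camera adjusted p = 9.37e-10, adjusted p = 0.161 with an estimated correlation). The erythroid list, none of 5 called by limma, had a median difference of -1.29 (5 at an unadjusted p under 0.05, camera adjusted p = 2.95e-05, adjusted p = 0.161 with an estimated correlation). The test called 13 genes, 11 upward in females and 2 downward, or 26 and 10 with scaling, and other groupings, with the common sex effect taken out, called up to 2. It called 4 with a replicate block, 4 with the carry-over covariate and 117 with limma voom. The count was 75, 8 and 22 without 3-month female replicate 1, 2 or 5, 8, 5 and 20 without 24-month female replicate 2, 3 or 5, 21 and 35 without 3-month male replicate 1 or 2, and 23 and 5 without 24-month male replicate 2 or 5.

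**Figure D1:**
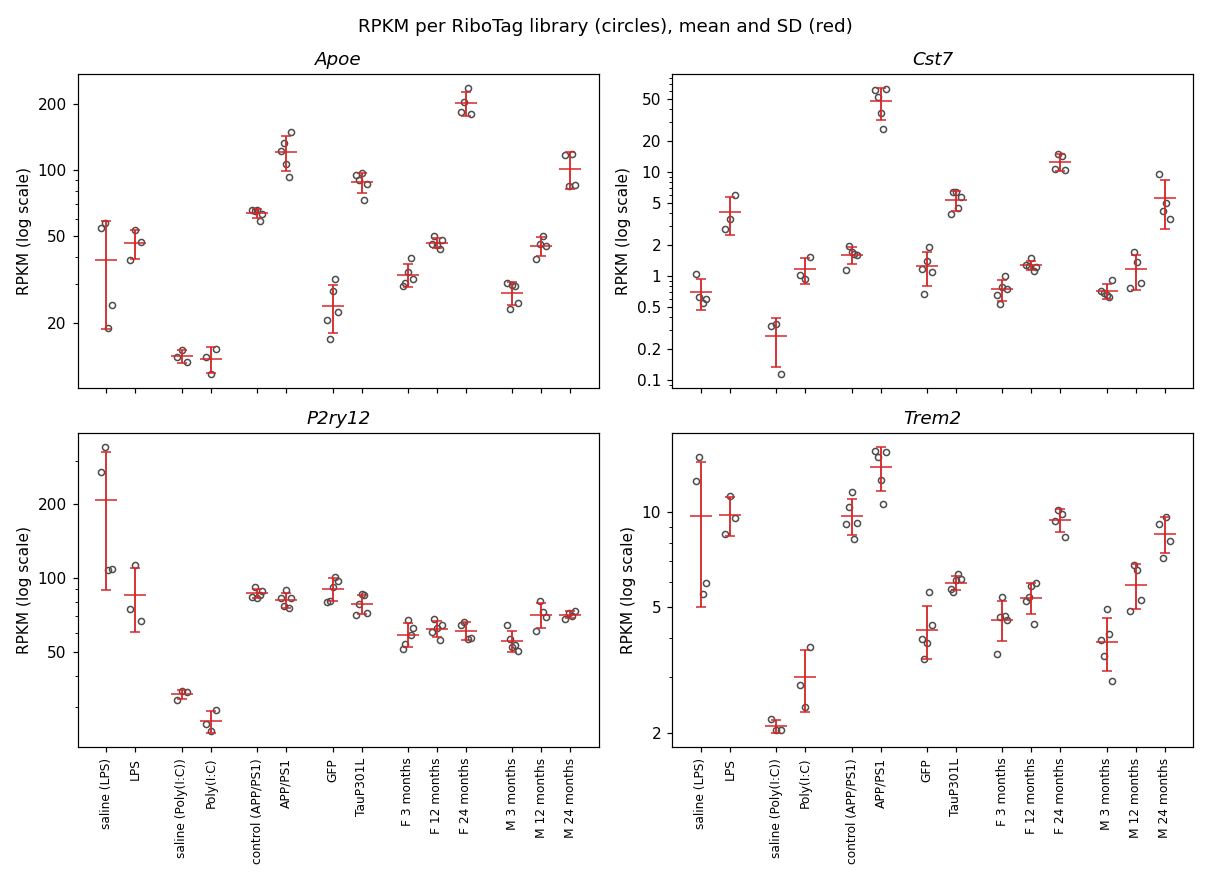
RPKM (log axis) of Apoe, Cst7, P2ry12 and Trem2 in every RiboTag library by group, with circles for libraries and red bars for mean and SD. Apoe and Cst7 were higher in APP/PS1, TauP301L and 24-month groups, and for Apoe, P2ry12 and Trem2 the 4 saline libraries of the LPS study split into a high and a low pair.

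The series title names a pathway common to ageing, amyloid and tau, and the 3 comparisons used separate control libraries. By Xist and Ddx3y the amyloid and tau libraries, like those of LPS and Poly(I:C), read as male, so female ageing was set against males. Of 12430 genes tested in all 3, 23 entries were higher in 24-month females, APP/PS1 and TauP301L, against 0.0782 expected if the lists were independent, and 1 was lower against 0.0235. The higher ones included Apoe at 2.57, 0.90 and 1.86 for ageing, amyloid and tau, Ccl3 at 3.14, 2.78 and 1.92, Cst7 at 2.94, 4.16 and 1.51, Spp1 at 3.66, 1.11 and 1.77, Axl at 1.12, 0.82 and 1.03, and Lpl at 0.88, 1.02 and 0.73. Clec7a entered under both of its identifiers, at 2.20, 1.57 and 1.95 under the first and 2.02, 1.42 and 1.55 under ENSMUSG00000102040. Lyz2, Cd63, Cd9, Ctsb, Ctsz, Lilrb4, Gfap, Fam46c and Ctsl were also among them, as were Tyrobp, Tlr2, Cd52, Ctsd, Lgals3bp and Mpeg1. The lower one, Sowaha, had -0.34, -0.23 and -0.30, and was chosen after its values were seen. With 24-month males in place of females the same 24 entries were shared, 23 higher and 1 lower, which are 23 symbols because Clec7a counts under both identifiers. By pairs, amyloid and tau shared 24 higher entries against 0.478 expected (one-sided Fisher exact p = 8.64e-36), female ageing and amyloid 59 against 12.0 (p = 2.55e-34), and female ageing and tau 64 against 14.4 (p = 7.79e-33). Sharing was not particular to these 3, since Poly(I:C) shared 25 higher genes with amyloid against 3.37 expected (one-sided Fisher exact p = 1.94e-16), 28 with tau against 4.51 (p = 8.5e-16) and 563 with female ageing against 124.0 (p = 2.21e-301), and LPS in pulldowns shared 114 with female ageing against 26.1 (p = 4.04e-58). Across genes, which are not independent replicates, the log2 fold changes of female ageing correlated at 0.53 with Poly(I:C) and 0.54 with LPS in pulldowns, against 0.35 with amyloid and 0.40 with tau. For male ageing these correlations were 0.55, 0.52, 0.22 and 0.40. Apoe was not among the genes called after Poly(I:C) or after LPS in pulldowns. Leaving out GFP replicate 5 raised the number shared by ageing in females, amyloid and tau from 24 to 37. The number was 94 with limma voom, 6 with a replicate block and 5 at a fold change of at least 2.

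**Figure D2:**
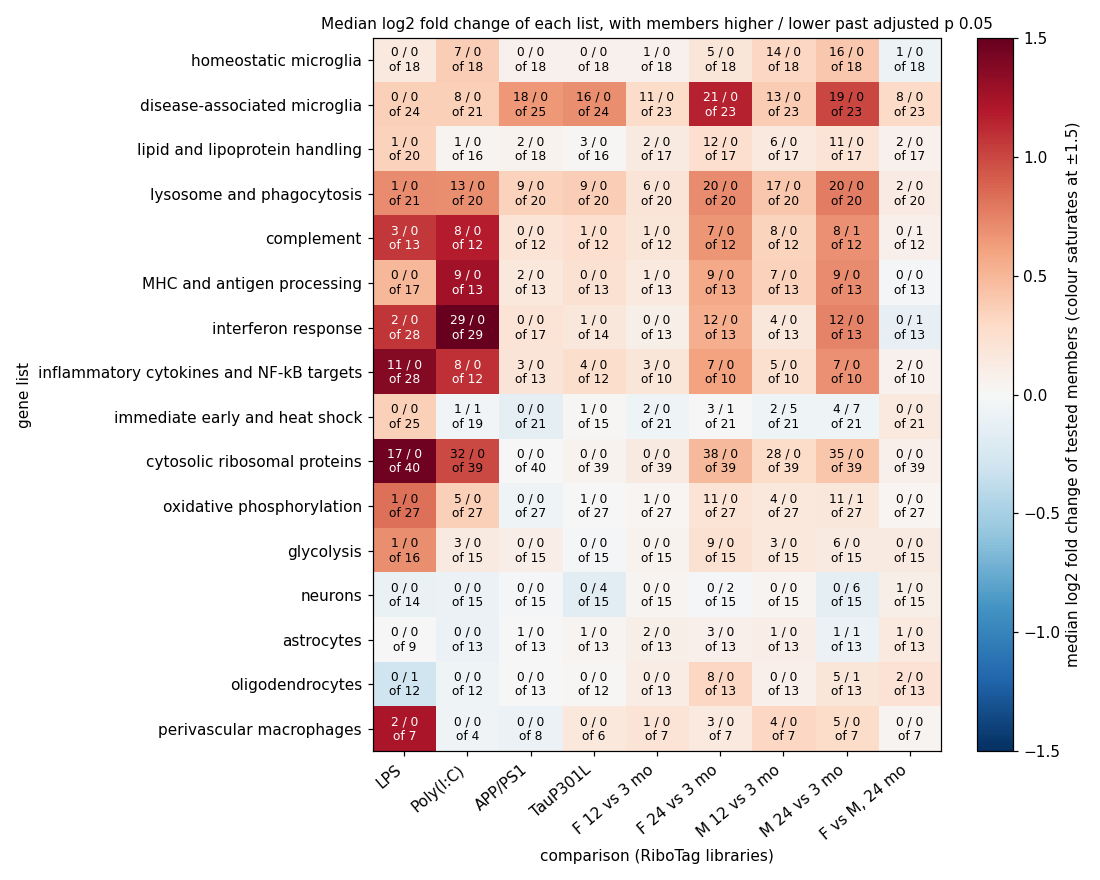
Median log2 fold change (colour) of 16 gene lists (vertical axis) in 9 RiboTag comparisons (horizontal axis), with the members called higher and lower out of those tested. Members of the disease-associated and lysosomal lists were called higher in amyloid, tau and ageing and also after Poly(I:C), where the interferon list had its highest median.

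**Figure D3:**
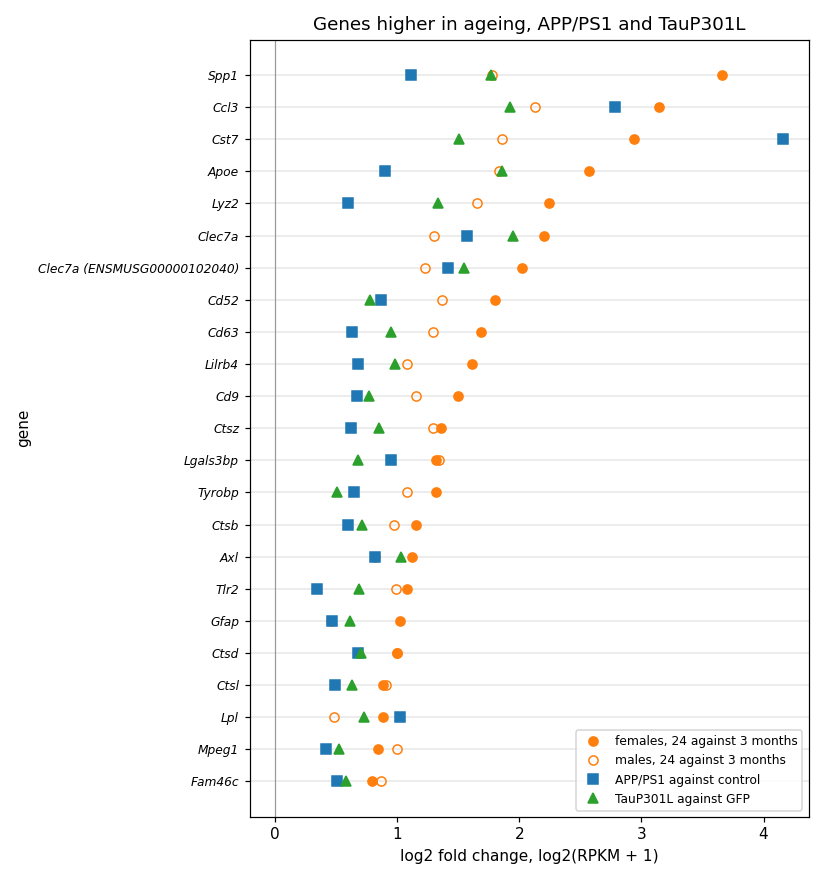
Log2 fold change (horizontal axis) of each gene (vertical axis) higher in 24-month females, APP/PS1 and TauP301L, with males at 24 months as open circles. Each symbol is the limma estimate of 1 comparison and no error bars are drawn.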

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

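The tests of S100a8 and S100a9 induction, of neutrophils in the forebrain, of the 3 explanations for Apoe, of microglial RNA in old females and of a sex difference at all ages, in the list and in Spp1 and Clec7a, and the regroupings for differences of effects were chosen after the result was seen. The tests on further neutrophil genes and with the carry-over covariate were set before.

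In the saline sorted libraries S100a8 and S100a9 stood at 4763 and 4791 RPKM, against 3.59 and 3.94 in the pulldown, and Ngp and Camp at 892 and 256, although the 7AAD-negative CD11b-positive CD45 low or intermediate gate should leave out cells with high CD45. Induction by dissociation of S100a8 and S100a9 alone is argued against by the granule genes Ngp, Camp and Ltf (119 RPKM in sorted cells), although 3 others, Elane, Mpo and Prtn3, were at 0, 0.0334 and 0, so that the median of 59.4 over the 6 lies between an abundant and an absent set. An origin of this RNA in neutrophils of the whole forebrain cannot be told apart from one in the isolation, because the median ratio of input to sorted level, 0.00166 over 15 genes, was low also for homeostatic microglial genes (0.00808), which the bulk tissue dilutes. Neutrophils among the sorted cells may be the source, since 10 further neutrophil genes had a median log2 difference of -3.42 between pulldown and sorted cells. No biological explanation was tested, because the design holds no group that would separate sorted neutrophils from microglia that express their genes, and a wider induction in microglia stays open.

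Apoe was higher in saline RiboTag than in saline sorted libraries by 1.99. A general excess of microglial transcripts in the pulldown is argued against by the homeostatic list, with a median log2 difference of -1.81. Macrophages at the brain's borders, tagged through Cx3cr1 and lost by the CD45 gate, may contribute, since the perivascular macrophage list had a median of 1.89, with Mrc1 at 9.95 and Pf4 at 8.09 RPKM in the pulldown against 1.81 and 0.0140 in sorted cells. Carry-over of bulk RNA cannot be told apart from microglial Apoe, because Apoe was 0.86 higher in the pulldown than in the input with adjusted p = 0.0535. An effect of the isolation itself on Apoe stays open and was not tested.

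The disease-associated list was higher in females than in males at 24 months, with a median of 0.29. More microglial RNA in the pulldowns of old females is argued against by the homeostatic list, whose median difference was -0.08. With the carry-over covariate the list kept 46.7% of its median, as carry-over predicts, and the median became 0.14 with a camera adjusted p of 1.6e-17. This cannot tell carry-over from a sex difference in the covariate's own markers, such as Snap25 at 51.1 RPKM in females and 43.4 in males. Bulk input of the LPS study held less Apoe and Cst7 (19.0 and 0.274 RPKM) than 24-month female pulldowns (202 and 12.5). In old females it was not measured, so carry-over stays open. A sex difference present at all ages is argued against for Spp1 and Clec7a by differences in the ageing effect of 1.88 and 0.90 (adjusted p = 2.57e-05 and 0.00011), and for the list it cannot be told apart from one that grows with age, because the 3-month median was 28.6% of that at 24 months (12-month median -0.02, Apoe then 0.05), while the difference in the ageing effect had adjusted p = 0.161 with an estimated correlation for the list and 0.0547 for Apoe. The biological difference by sex that the design names stays open beside these and was not tested apart from carry-over.

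Among 120 groups of 4 to 10 libraries checked, 3 held a library far from the others, where chance gives about 1 in 20 groups. Tyrobp was at 170 RPKM in APP/PS1 replicate 4 and at 221 to 241 in the other 4. Tyrobp was at 65.8 RPKM in the 12-month female replicate 4 and at 84.2 to 88.7 in the others. P2ry12 was at 3.40 RPKM in input replicate 1 and at 4.32 to 4.42 in the others.

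The LPS response differed between pulldown and sorted cells for 36 genes by the interaction test. Differences of pulldown minus sorted response were 3.95 for Snord71, 3.32 for Mir181b-2, 2.62 for Fam167b, 2.35 for Coq9 and 2.13 for Srpk3. They were -3.94 for Asprv1, -3.69 for Prok2, -3.56 for Steap4, -3.44 for Il1r2, -3.42 for Ifitm1, -2.86 for Ch25h, -2.64 for Hcar2 and -2.58 for Il1f9. Without each library in turn Steap4 alone of these 13 kept an adjusted p under 0.05. With the LPS effect common to both methods taken out, 3 of 100 regroupings, the real one included, gave as many genes. The highest other count was 148, so chance and sample structure stay open, and neutrophil RNA of sorted cells was not tested apart.

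The ageing effect differed between the sexes for 13 genes by the interaction test. Differences of female minus male effect were 1.88 for Spp1, 1.01 for Ccl3, 0.90 for Clec7a, 0.57 for Tex40, 0.56 for Gfap, 0.54 for Mfap3, 0.45 for Siae, 0.39 for Sprn, 0.33 for Ubr3 and -0.38 for Tbcc. Spp1, Clec7a and Gfap kept an adjusted p under 0.05 without each library in turn and the other 7 did not. With the common sex effect taken out, 1 of 100 regroupings, the real one, gave as many genes (highest other 2), which argues against chance.

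Up to 100 regroupings of the same libraries were counted per comparison, the real one included. Chance is argued against where, of those drawn, only the real one gave as many genes. This held for pulldown against input (8602, highest other 0), pulldown against sorted cells (5555, highest other 2747), LPS in pulldowns (189, highest other 0), APP/PS1 (189, highest other 1) and TauP301L (161, highest other 1). It also held for the female steps from 3 to 12 (418, highest other 4), 3 to 24 (2853, highest other 1521) and 12 to 24 months (773, highest other 539), and for the male ones (1969, 3321 and 1382, highest others 1786, 2645 and 1). Females against males at 12 months (82, highest other 24) and 24 months (116, highest other 2) were alike in this. For the difference between APP/PS1 and TauP301L, with the effect common to both taken out, it held as well (117, highest other 1). For the sexes at 3 months (41) 2 of 100 regroupings, the real one included, gave as many, with a highest other of 61, so chance stays open for this count. For LPS in sorted cells (1227, highest other 578) and for Poly(I:C) (878, highest other 2), 3 libraries against 3 allow 10 groupings, too few for a share under 0.05.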

How the results depend on the processing

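Limma voom on recovered reads and the fit without saline RiboTag replicates 3 and 4 were tests chosen after the result was seen, and the other alternatives were fixed before the data were examined. A count is taken as moved where it changed by over 1.5 times. Of the counts under alternatives that kept all libraries or left out a set pair, 99 stayed within that range and 76 moved, and with 1 library left out 126 stayed and 89 moved. For named genes 5312 values kept direction and side of the threshold, 671 lost the call and 1 reversed, and 6070 and 983 did so with 1 library left out. For gene lists these were 1481, 261 and 3, and 1655 and 139. A fold limit lowers a count by construction, and for the other settings the cause was not tested. In the LPS study the shared fit used 1 spread, although sorted replicates varied more than pulldown replicates. Such a spread is too high for pulldowns and too low for sorted cells. The counts moved that way, up for pulldowns and down for sorted cells when each was fitted alone. These fits also differ in the number of libraries and the genes tested, which was not told apart. The 37.3% of 2-fold changes recovered in the simulated LPS pulldowns did not include this difference in spread.

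A mean of at least 5 RPKM gave 2501 genes for pulldown against input, 2044 against sorted cells, 300 for LPS in pulldowns, 763 in sorted cells, 16 for their difference, 375 for Poly(I:C), 363 for APP/PS1, 275 for TauP301L and 241 for their difference. For ageing it gave 1293 in females and 1417 in males at 24 against 3 months, 389 in females at 24 against 12, 1021 in males at 12 against 3, and 7 for the sex difference in ageing. Without a filter the counts were 11861 for pulldown against sorted cells, 85 for APP/PS1, 81 for TauP301L, 59 for their difference, and 229 and 1197 for females and males at 12 against 3 months.

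A fold change of at least 2 gave 1895 for pulldown against input, 369 for Poly(I:C), 11 for APP/PS1, 9 for TauP301L, 3 for their difference and 5 shared by ageing, amyloid and tau. In females it gave 7, 52 and 22 for 12 against 3, 24 against 3 and 24 against 12 months, in males 4, 44 and 16, between the sexes 8, 11 and 12 at 3, 12 and 24 months, and 3 for the sex difference in ageing.

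Median-of-ratios scaling gave 47 for LPS in pulldowns, 285 for TauP301L, 245 for the difference between APP/PS1 and TauP301L, 1272 for males at 12 against 3 months and 36 for the sex difference in ageing. A pseudocount of 0.1 RPKM gave 56 for the difference in LPS response. With a fit of only the compared groups the counts were 1720 for LPS in pulldowns, 72 in sorted cells, 107 for females at 12 against 3 months, 507 and 2073 for males at 12 and 24 against 3 months, and 16 and 68 between the sexes at 3 and 24 months.

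Limma voom gave 79 for LPS in pulldowns, 423 for APP/PS1, 687 for TauP301L, 365 for their difference, 85, 141 and 234 between the sexes at 3, 12 and 24 months, 117 for the sex difference in ageing and 94 shared. Without saline RiboTag replicates 3 and 4 there were 3623 for pulldown against sorted cells, 12 for LPS in pulldowns and, by limma, 0 for the difference in LPS response (821 at an unadjusted p under 0.05), where the median of the homeostatic list reversed to -0.126.

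The carry-over covariate gave 92 for TauP301L, 52 and 1257 for females at 12 and 24 against 3 months, 672 for males at 12 against 3 and 621 at 24 against 12, 31 between the sexes at 24 months and 4 for the sex difference in ageing. Under it Aldoc reversed to -0.0766 for females at 24 against 3 months, and between the sexes at 24 months the glycolysis list reversed to a median of -0.047 and the cytosolic ribosomal protein list to -0.026.

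Replicate numbers were not used to pair libraries. Correlations of same-numbered libraries ran from -0.55 to 0.13, and from -0.11 to -0.01 for saline pulldown and input. Such values cannot show whether a pulldown and an input came from the same animal. A block on the number gave 48 for LPS in pulldowns, 767 in sorted cells, 1 for their difference, 47 for APP/PS1, 22 for TauP301L, 44 for their difference, 4 for the sex difference in ageing and 6 shared.

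With each library left out in turn the counts ranged from 7765 to 9103 for pulldown against input, 4583 to 5712 against sorted cells, 3 to 270 for LPS in pulldowns, 1170 to 1633 in sorted cells and 1 to 180 for their difference. They ranged from 538 to 1142 for Poly(I:C), 62 to 243 for APP/PS1, 55 to 275 for TauP301L, 38 to 178 for their difference and 16 to 37 shared. In females they were 144 to 808, 2117 to 2635 and 505 to 872 for 12 against 3, 24 against 3 and 24 against 12 months, and in males 825 to 2714, 2589 to 3419 and 804 to 1211. Between the sexes they were 24 to 96, 40 to 87 and 59 to 131 at 3, 12 and 24 months, and 5 to 75 for the sex difference in ageing.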

Other observations

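No tests in this part were chosen after the result was seen, and the values are given without explanation.

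In the LPS study the saline RiboTag libraries spread over a mean log2 level of the homeostatic list from 5.21 to 6.68, and those of LPS from 5.87 to 6.29. The homeostatic list averaged 7.48 in saline sorted and 1.99 in input libraries. Its mean was 4.14 in the saline pulldowns of the Poly(I:C) study and 5.59 in the controls of APP/PS1.

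All 37 genes of the mitochondrial chromosome were listed at 0 in every library. The 24-month males held 1 erythroid gene called higher out of 5, while 4 of 5 were lower in 24-month females, and the interaction test gave the erythroid list a camera adjusted p of 2.95e-05 and adjusted p = 0.161 with an estimated correlation.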
